A study of Homo sapiens with 15 samples.

How the data were processed

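The series measured polyadenylated RNA in 15 bulk RNA-seq libraries from cultures labelled SH-SY5Y, a human neuroblastoma line. Per the labels' protocols, cells were harvested 72 hours after lipid transfection with an empty plasmid or with the same plasmid carrying 1 of 2 suppressor tRNA genes, Arg-TCA-3-1 or Arg-TCA-4-1. Each of the 3 groups held 5 libraries, numbered 1 to 5 in the labels. Nothing in the labels says that these were separate cultures or that a number marks a shared day, so p-values measure only the spread between these libraries, which may be technical.

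The deposited values were raw counts per gene, 1 table per library with the same 28395 NCBI gene identifiers. Per the submitters' processing notes, the authors used HISAT2, featureCounts and the hg38 build, and no versions are given in the sources used here. Strand handling and the treatment of reads that map to several places are not given in the sources used here, so genes that overlap, lie antisense to each other or have near-identical copies are uncertain. Gene symbols and coordinates came from the RefSeq GRCh38.p14 gene table, which named 27745 identifiers. A further 20 were named through GENCODE 29, and 630 stayed unnamed. Stop codons, GC content and transcript length came from GENCODE 29.

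Differential expression was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts as deposited, with TMM factors, the filterByExpr filter and 1 fit of all 15 libraries. It tested 15410 genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fixed gene lists, 29 in all, were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation was an alternative, as was fry, which tests a list against no change and not against the other genes. Genes whose annotated coding transcripts all end in UGA were compared with genes ending in UAA or UAG by camera, adjusted over the 3 comparisons. Library totals, detected genes, the share of counts in the 100 most abundant genes and the mitochondrial share were compared with two-sided exact permutation tests, and shares of called UGA genes with two-sided Fisher's exact tests.

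The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The test of the mitochondrial share and the Fisher's exact tests were not among these fixed tests. Nor were the refitted library splits, the chi-square of library pairs, the screen for outlying libraries or the adjustment over a list alone. The spline correction and split controls applied to the heat shock and immediate early lists were not either. Per comparison and direction the rule takes the 10 genes of largest change among called genes with a mean log2 CPM of at least 1 whose 5 libraries of a group all lie on the same side of the other group's mean. It adds up to 4 called members of each list, or 2 members where a list passed with none called, and 12 genes named in advance, among them HSPA1A, which the count filter removed. Where fewer than 5 genes were called in a direction it takes the 5 of smallest p, which did not occur. The text takes these in order of p. How many it takes, 6 per direction, 2 per list past the threshold and 4 from the other lists, was set after the values were seen. Some genes that the rule or the lists take are not reported here. Any other gene named is said to have been chosen after its values were seen.

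The alternatives were DESeq2 size factors, no count filter, a filter at a CPM above 1 in at least 5 libraries, DESeq2 1.42.0 (Wald test), limma voom, a fit of only the 10 libraries compared, size thresholds of 1 and 0.26 on the log2 scale, the replicate number as a term, and leaving out each library. Thinning all libraries to the smallest total, leaving out libraries in the stop codon test, size factors in the stop codon test, and fitting Arg-TCA-3-1 against empty vector without Arg-TCA-4-1 replicate 1 were added after seeing the data.

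Both comparisons with empty vector share the same 5 control libraries. All 15 libraries were therefore simulated 20 times with no group changed, controls included, each gene drawn independently at its mean level over all libraries. The real controls were also split into 2 and 3 in all 20 ways. For each comparison 100 of the 126 splits of its 10 libraries were refitted, the real one included. On simulated counts with 200 changed genes of known fold, taken from genes with at least 50 expected counts, the test for Arg-TCA-3-1 against empty vector (15410 genes) recovered 32% of genes changed 1.1-fold, 80% at 1.2-fold, 98% at 1.5-fold and 100% at 2-fold. For Arg-TCA-4-1 against empty vector these shares were 38%, 78%, 94% and 100%, and for Arg-TCA-4-1 against Arg-TCA-3-1 they were 42%, 88%, 98% and 100%. Of the unchanged genes in those simulations, 7, 12 and 8 were called. Intervals on counts are exact and cover counting error only.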

Results

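Polyadenylated RNA was counted per gene in 15 libraries labelled SH-SY5Y, 5 with empty vector, 5 with Arg-TCA-3-1 and 5 with Arg-TCA-4-1. Both tRNAs are arginine tRNAs whose anticodon was changed to read the UGA stop codon. The libraries held 19720707 to 33776284 counts each, with a mean of 23.5 ± 3.01 M (SD, n = 5) with empty vector, 26.4 ± 4.65 M with Arg-TCA-3-1 and 22.5 ± 1.70 M with Arg-TCA-4-1. Between 18985 and 19710 genes had a count in a library. No measure of depth or detection differed between groups by an exact permutation test after adjustment. The share of counts in the 100 most abundant genes was 16.7% ± 0.197 (SD, n = 5) with Arg-TCA-4-1 and 16.3% ± 0.0866 with empty vector (exact permutation p = 0.00794, the smallest that 5 against 5 can give, and 0.0595 after adjustment over 15 tests). The mitochondrial share was 5.23% ± 0.117 and 4.88% ± 0.123 in the same groups, with the same exact p values. Pairs of libraries of a group differed by a chi-square of 1.84 to 4.68 per degree of freedom over 30 pairs, so none agreed within sampling noise.

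Each suppressor tRNA gene was read in its own group. TRR-TCG3-1, the genomic gene matching Arg-TCA-3-1 (chromosome 17, 75035113 to 75035185, GRCh38, in an intron of KCTD2), had 444, 683, 742, 531 and 561 counts in the 5 Arg-TCA-3-1 libraries, 1, 0, 0, 2 and 0 with empty vector, and 2, 1, 0, 0 and 0 with Arg-TCA-4-1. Summed over the group, its level with Arg-TCA-3-1 was 879 times that with empty vector (exact 95% counting interval 300 to 4262). TRR-TCG4-1 (chromosome 6, 26299677 to 26299749) had 338, 398, 417, 432 and 393 counts with Arg-TCA-4-1 and 0 in all other libraries, at least 689-fold higher than with empty vector against a floor of 3 counts over the group. Counts of polyadenylated RNA on a tRNA gene do not measure mature tRNA. All 15 libraries matched their labels by these genes.

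**Figure D1:**
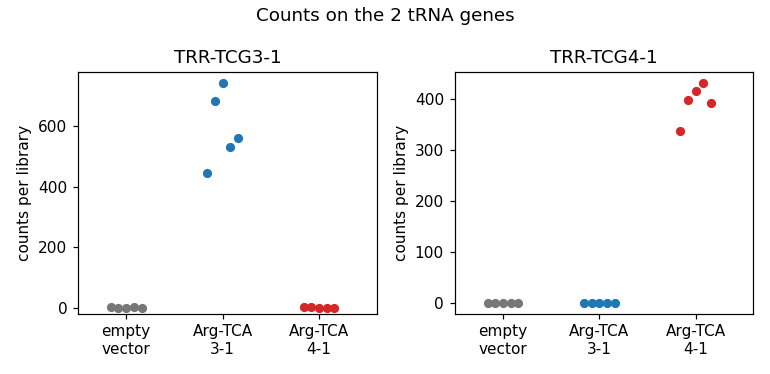
Counts per library on TRR-TCG3-1 (left) and TRR-TCG4-1 (right), 1 point per library, 5 libraries per group. TRR-TCG3-1 held 444 to 742 counts in the Arg-TCA-3-1 libraries and at most 2 elsewhere, and TRR-TCG4-1 held 338 to 432 in the Arg-TCA-4-1 libraries and 0 elsewhere.

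Of 25 fixed adrenergic neuroblast markers, 13 lay under 1 CPM in every library, among them TH, the rate-limiting enzyme of catecholamine synthesis, at 0.0143 ± 0.0309 CPM (SD, n = 15), and CHGA at 0 in all libraries. GATA2 at 123.6 ± 6.19 CPM, GATA3 at 103.5 ± 2.70 CPM and TBX2 at 69.1 ± 1.96 CPM of the same list were present, and GATA2 fell by 0.14 ± 0.03 on the log2 scale with Arg-TCA-3-1 (edgeR adjusted p = 0.00202). Of 15 epithelial and kidney line markers 10 lay under 1 CPM in every library, with KRT18 at 51.2 ± 1.53 CPM and PAX2 at 22.1 ± 1.48 CPM. Of 27 mesenchymal neuroblastoma markers 16 had a mean of at least 10 CPM, 14 of them in every library, and 7 lay under 1 CPM in every library. Of 24 neuronal differentiation genes 7 had at least 10 CPM in every library and 5 lay under 1 CPM in every library. The neurofilament genes NEFM and NEFL stood at 3546 ± 158 and 490.4 ± 19.0 CPM. IRS4, an insulin receptor substrate on none of the lists, stood at 716.6 ± 10.8 CPM with empty vector, 685.5 ± 23.2 CPM with Arg-TCA-3-1 and 732.4 ± 18.4 CPM with Arg-TCA-4-1 (SD, n = 5 each). TH, CHGA, GATA2, GATA3, TBX2, KRT18, PAX2, NEFM, NEFL and IRS4 were chosen for this after their values were seen. The identity given by the label is therefore written as a label throughout.

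The first comparison asks what Arg-TCA-3-1, a tRNA whose anticodon reads the UGA stop codon, changed against empty vector. EGR1, an immediate early transcription factor (chromosome 5, 138465479 to 138469303, GRCh38), rose from 13.3 ± 1.18 to 67.8 ± 10.5 CPM (SD, n = 5 each; log2 fold change 2.35 ± 0.08 SE). FOS, another immediate early gene (chromosome 14, 75278828 to 75282230), rose from 8.71 ± 0.643 to 20.1 ± 3.18 CPM, and HSPA6, an inducible heat shock protein with a near-identical copy (chromosome 1, 161524540 to 161526894), from 1.37 ± 0.149 to 5.62 ± 0.723 CPM. DNAJB1, a cochaperone of HSP70 (chromosome 19, 14514769 to 14560391), rose by 0.46 ± 0.02 on the log2 scale. KCTD2 (chromosome 17, 75032571 to 75065886), whose intron holds TRR-TCG3-1, rose from 72.2 ± 1.68 to 149.8 ± 7.34 CPM.

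By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 549 of 15410 genes changed, 263 higher and 286 lower. Most changes were small: the median absolute log2 fold change of called genes was 0.15, 95 reached 0.26 and 20 reached 1. The adjusted p of edgeR's test was 6.84e-21 for EGR1, 2.79e-11 for FOS, 7.45e-10 for HSPA6, 5.18e-16 for DNAJB1 and 4.11e-23 for KCTD2. SNORD139, a small nucleolar RNA, rose by 0.96 ± 0.11, and CCN1, a matricellular protein gene, by 0.42 ± 0.04. On the lower side, CDHR4 (chromosome 3, 49790732 to 49802914) fell from 8.21 ± 1.03 to 0.533 ± 0.245 CPM (log2 fold change -4.0 ± 0.19). ANXA2R-OT1 fell by 1.23 ± 0.14, FAM156A, which has a near-identical copy and is uncertain, by 1.17 ± 0.22, DDX19A-DT by 0.67 ± 0.16 and ZNF460 by 0.50 ± 0.10. LOC102724594, which has a near-identical copy and is uncertain, had a log2 fold change of -3.25 ± 0.76, and its call was lost without empty vector replicate 5 (log2 fold change -2.13) and with limma voom.

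Of the cytosolic heat shock list, 11 of 15 measured members rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 2.28e-17, and 0.0138 with an estimated correlation). HSPH1, an HSP110 chaperone, rose by 0.18 ± 0.03. HSPA1A had 75 counts in all 15 libraries and was not tested. It lies between 29 and 33 Mb of chromosome 6, where 63 of 139 protein-coding genes had no count, so its total is not taken as a level of expression. Of 18 immediate early genes 5 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 2.96e-05), with an adjusted p = 0.274 with an estimated correlation. Ribosomal protein genes were lower as a list, 2 of 74 falling (2 adjusted over the list alone; adjusted p = 5.83e-04, but adjusted p = 0.805 with an estimated correlation), with RPS14 falling by 0.08 ± 0.02. That list had an adjusted p of 0.319 without empty vector replicate 1. The 13 mitochondrially encoded mRNAs (0 called, also adjusted over the list alone; adjusted p = 0.0183, and adjusted p = 0.801 with an estimated correlation) had CYTB at 0.07 ± 0.03 and ND1 at 0.08 ± 0.03, neither called, though each was in 2 of 8 other settings and without Arg-TCA-3-1 replicate 1. Of 31 proteasome subunits PSMD4 rose by 0.08 ± 0.02 (2 adjusted over the list alone; adjusted p = 0.028, and adjusted p = 0.805 with an estimated correlation). Of 28 genes of tRNA synthesis and processing POP1 rose by 0.19 ± 0.05 (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.028, and adjusted p = 0.801 with an estimated correlation).

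Several of these weaker calls did not hold when single libraries were left out. Of the 6 lists, 2 passed without empty vector replicate 1 and 3 passed a fit without Arg-TCA-3-1 replicate 5. The mitochondrial mRNAs had an adjusted p of 0.126 without empty vector replicate 1, 0.124 without empty vector replicate 4, 0.147 without Arg-TCA-3-1 replicate 3 and 0.193 without Arg-TCA-3-1 replicate 5. The proteasome list had an adjusted p of 0.0913, 0.0509 and 0.114 without empty vector replicates 1, 3 and 4, and of 0.108, 0.0681 and 0.0899 without Arg-TCA-3-1 replicates 2, 3 and 5. The tRNA synthesis list had an adjusted p of 0.0913 and 0.0595 without empty vector replicates 1 and 3, and of 0.108 and 0.107 without Arg-TCA-3-1 replicates 2 and 5. The calls of PSMD4 (log2 fold change 0.07 to 0.10 with a library left out) and POP1 (0.16 to 0.20) were lost without empty vector replicates 1, 3, 4 or 5 or Arg-TCA-3-1 replicates 2, 3 or 5.

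Among the other 23 lists, none of which passed (adjusted p from 0.0651 to 0.995), 11 list members rose and 16 fell. Of these lists, proliferation (adjusted p = 0.0651) had an adjusted p of 0.0401 with the replicate number as a term and 0.0449 thinned to the smallest total, and passed in 2 of 10 fits with a library left out. Against no change, which is what fry tests, in place of against the other genes, the adjusted p was 0.0459 for proliferation and 0.00640 for selenoproteins (adjusted p = 0.0710 by camera). DCP2, the catalytic subunit of mRNA decapping, fell by 0.25 ± 0.03, SNHG8 rose by 0.31 ± 0.05 and SESN2, a stress-induced sestrin, rose by 0.20 ± 0.03. Of genes named in advance none was called: GRN, the progranulin gene, stood at 0.06 ± 0.03 (adjusted p = 0.202), ETF1, the release factor that reads stop codons, at -0.02 ± 0.03, UPF1 at -0.01 ± 0.02, ATF4 at 0.06 ± 0.02, RARS1, the arginyl-tRNA synthetase, at 0.07 ± 0.02 (called without Arg-TCA-3-1 replicate 1), HSPA5 at -0.0035 ± 0.019 and CDKN1A at 0.09 ± 0.03. GSPT1, ASNS, DDIT3 and GADD45B were likewise not called. The count was 333 without empty vector replicate 1, 344 without empty vector replicate 3, 341 without empty vector replicate 4, 361 without empty vector replicate 5, 337 without Arg-TCA-3-1 replicate 2 and 345 without Arg-TCA-3-1 replicate 3. It was 876 in a fit of only these 10 libraries and 900 without Arg-TCA-4-1 replicate 1, a library of neither group that shares the estimate of the spread.

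The second comparison asks the same of Arg-TCA-4-1. EGR1 rose from 13.3 ± 1.18 to 103.4 ± 8.77 CPM (SD, n = 5 each; log2 fold change 2.96 ± 0.08 SE), FOS from 8.71 ± 0.643 to 31.6 ± 3.91 CPM and HSPA6 from 1.37 ± 0.149 to 5.38 ± 1.84 CPM. CDHR4 fell from 8.21 ± 1.03 to 0.703 ± 0.126 CPM. Of 13 mitochondrially encoded mRNAs 9 rose, among them ATP8 by 0.19 ± 0.03 and COX3 by 0.17 ± 0.03. KCTD2 stood at 0.03 ± 0.03, not called.

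By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 650 genes changed, 218 higher and 432 lower, with a median absolute log2 fold change of 0.14 among them. A log2 fold change of at least 0.26 was reached by 83 of them and of at least 1 by 15. The adjusted p of edgeR's test was 5.26e-24 for EGR1, 6.70e-17 for FOS, 5.50e-09 for HSPA6 and 6.32e-16 for CDHR4. SNORA51 and SNORD139, small nucleolar RNAs, rose by 1.06 ± 0.18 and 0.84 ± 0.12, and CCN1 by 0.41 ± 0.04. ANXA2R-OT1 fell by 0.96 ± 0.14, ZNF460 by 0.55 ± 0.10 and ANKRD36BP1 by 0.52 ± 0.10. FSIP2 fell by 0.58 ± 0.15, a call lost without empty vector replicates 1 or 2 or Arg-TCA-4-1 replicates 2, 3 or 5 (-0.68 to -0.51 with a library left out). RN7SL2, which has near-identical copies and is uncertain, fell by 0.48 ± 0.12, a call lost without Arg-TCA-4-1 replicate 5 (-0.35) and with DESeq2.

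Heat shock genes rose in 10 of 15 cases and fell in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 1.87e-14, and 0.0167 with an estimated correlation), DNAJB1 by 0.15 ± 0.02 and HSPB1, a small heat shock protein, by 0.26 ± 0.05. The mitochondrial mRNAs passed at 3.06e-19 (11 higher adjusted over the list alone; adjusted p = 0.0457 with an estimated correlation). The mitochondrial share of counts was 5.23% with Arg-TCA-4-1 and 4.88% with empty vector. Of 18 immediate early genes 7 rose and ATF3 fell, by 0.20 ± 0.02 (8 and 1 adjusted over the list alone; adjusted p = 3.08e-09, and 0.0457 with an estimated correlation). Cholesterol synthesis genes were higher as a list, with 1 of 23 called (4 adjusted over the list alone; adjusted p = 5.18e-04, and 0.0167 with an estimated correlation).

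The other 6 lists that passed lost that with an estimated correlation. They were ribosomal proteins, higher with RPL23A rising by 0.09 ± 0.02 (1 of 74, 5 adjusted over the list alone; adjusted p = 3.34e-08, then adjusted p = 0.460 with an estimated correlation), and hypoxia and glycolysis, lower with KDM3A falling by 0.15 ± 0.03 and ERO1A by 0.12 ± 0.03 (3 of 25, 8 adjusted over the list alone; adjusted p = 1.29e-05, then adjusted p = 0.460). The respiratory chain was higher with 0 of 39 called, also adjusted over the list alone (adjusted p = 4.57e-05, then adjusted p = 0.229), NDUFB10 standing at 0.07 ± 0.02 and NDUFA2 at 0.12 ± 0.04. Each of these 2 was called in 1 of 8 other settings, NDUFB10 also without Arg-TCA-4-1 replicate 1 and NDUFA2 without empty vector replicate 1. p53 targets were higher with BTG2 and CDKN1A, a cyclin-dependent kinase inhibitor, each rising by 0.20 ± 0.03 (4 of 22, 5 higher and 1 lower adjusted over the list alone; adjusted p = 9.31e-04, then adjusted p = 0.268). The integrated stress response was lower, with 5 of 28 falling and 1 rising (6 and 2 adjusted over the list alone; adjusted p = 0.0141, then adjusted p = 0.0629), PPP1R15A falling by 0.17 ± 0.03, and had an adjusted p of 0.0930 without Arg-TCA-4-1 replicate 1. Oxidative stress genes were higher with PRDX1 and TALDO1 each rising by 0.09 ± 0.02 (2 of 19, also adjusted over the list alone; adjusted p = 0.030, then adjusted p = 0.229), and had an adjusted p of 0.0544 without empty vector replicate 3, 0.0690 without Arg-TCA-4-1 replicate 3 and 0.0558 without Arg-TCA-4-1 replicate 5. The call of RPL23A was lost without empty vector replicates 3 or 5 (0.07 to 0.10 with a library left out), and that of ERO1A without empty vector replicates 1, 3 or 4 or Arg-TCA-4-1 replicates 4 or 5 (-0.14 to -0.10). That of TALDO1 was lost without empty vector replicates 1, 4 or 5 or Arg-TCA-4-1 replicates 2 or 5 (0.08 to 0.10) and with libraries thinned to the smallest total.

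The other 19 lists did not pass (adjusted p from 0.0517 to 0.965). Mesenchymal markers, higher at an adjusted p = 0.0517, had an adjusted p of 0.0311 with the CPM filter, 0.0225 with the replicate number as a term and 0.0185 thinned to the smallest total. They passed in 6 of 10 fits with a library left out, and had an adjusted p of 0.497 without Arg-TCA-4-1 replicate 1 and 0.466 with an estimated correlation. Selenoproteins (adjusted p = 0.0521) had an adjusted p of 0.0469 with the replicate number as a term, and they and nonsense-mediated decay factors (adjusted p = 0.0807) each passed in 1 of 10 fits with a library left out. Against no change, by fry, the adjusted p was 0.204 for mesenchymal markers, 0.00445 for selenoproteins and 0.0396 for nonsense-mediated decay factors. DCP2 fell by 0.25 ± 0.03 and SNHG16 by 0.18 ± 0.02. Of the genes named in advance CDKN1A was called higher and ASNS, the asparagine synthetase, fell by 0.09 ± 0.02, a call lost without empty vector replicates 3, 4 or 5 or Arg-TCA-4-1 replicates 2, 3 or 4 (-0.10 to -0.08). GRN stood at 0.07 ± 0.03 (adjusted p = 0.144), ETF1 at -0.04 ± 0.03, UPF1 at -0.06 ± 0.02, ATF4 at 0.07 ± 0.02 (adjusted p = 0.0555) and RARS1 at 0.02 ± 0.02, none called, and GSPT1, DDIT3, HSPA5 and GADD45B were not called either. ATF4 was called in 5 of 8 other settings and without Arg-TCA-4-1 replicate 1. The count was 1291 without Arg-TCA-4-1 replicate 1, of which 625 were among the 650, and 284 without Arg-TCA-4-1 replicate 5, of which 276 were. It was 430 without empty vector replicate 3, 402 without empty vector replicate 4 and 406 without empty vector replicate 5.

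**Figure D2:**
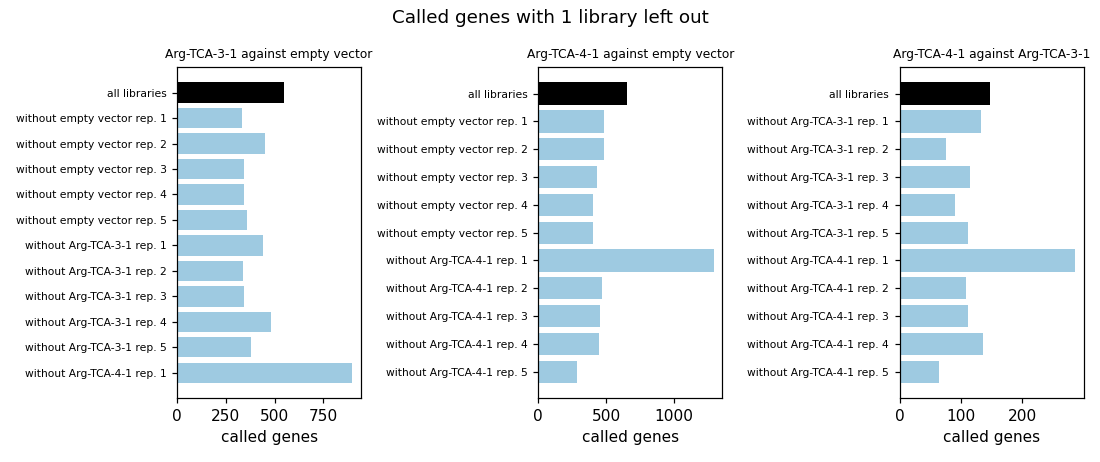
Number of called genes with all 15 libraries (black) and with each library left out in turn (blue), for the 3 comparisons. Without Arg-TCA-4-1 replicate 1 the count for Arg-TCA-4-1 against empty vector was 1291 against 650, and without Arg-TCA-4-1 replicate 5 it was 284.

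The changes of the 2 suppressor tRNAs were compared across genes. Of the genes called higher, 62 were shared, where 3.72 are expected of independent lists, and of those called lower 142, where 8.02 are expected. In opposite directions 0 were called. The lists are not independent, as both comparisons use the same controls, so these expected counts are not a fair reference. With unchanged groups simulated against shared simulated controls, a mean of 1.05 and 0.3 genes were called and 0.05 shared. Over 15410 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.491 and Spearman's rho 0.537. The same simulated groups and controls gave a mean r of 0.501 (0.474 to 0.522) and a mean rho of 0.449 (0.442 to 0.457). So r lay within the simulated range and rho above it. But r takes in the 2 tRNA genes, with log2 fold changes of 9.51 (TRR-TCG3-1) and 11.7 (TRR-TCG4-1), each in its own group only. Values so large in a single comparison lower r and hardly move rho. The simulation left both genes unchanged, and r without them was not computed. The value of r therefore cannot show whether the tRNAs share changes. The covariance was 0.0176 against a simulated mean of 0.00790 (0.00723 to 0.00859), a difference of 0.00967, and 70.5% of genes had the same sign in both comparisons, against 66.3% to 67.5%. The simulation drew genes independently of each other, so these ranges, that of rho included, leave out shifts that many genes of a library share. They may be too narrow, and values outside them do not by themselves exclude the shared controls as their source. With the controls split into 2 and 3, the mean r over 20 assignments was 0.180 and the mean covariance 0.00833, with 9 to 16 shared genes higher and 20 to 38 lower.

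**Figure D3:**
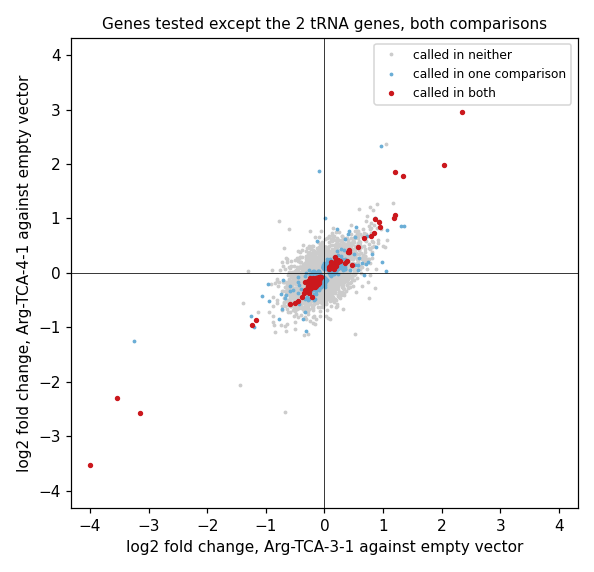
Log2 fold change against empty vector of the genes tested, 1 point per gene, Arg-TCA-3-1 on the x axis and Arg-TCA-4-1 on the y axis, colored by whether the gene was called in neither, 1 or both comparisons. The 2 tRNA genes lie outside the axes and are left out, and the 62 genes called higher and 142 called lower in both lie at the upper right and the lower left of the crossing lines at 0.

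The third comparison sets the 2 tRNAs against each other. EGR1 was higher with Arg-TCA-4-1 by 0.60 ± 0.06 on the log2 scale, FOSB by 0.70 ± 0.08 and FOS by 0.65 ± 0.08, while DNAJB1 was lower by a log2 fold change of -0.32 ± 0.02 and KCTD2 of -1.02 ± 0.03 (n = 5 each). BCYRN1, a neuronal noncoding RNA, was higher by 0.32 ± 0.06 and GLT8D2 by 0.31 ± 0.06. NPR3, a natriuretic peptide receptor, stood at -0.72 ± 0.11, STX1A, a syntaxin of synaptic vesicle release, at -0.28 ± 0.06 and EIF2AK3, the kinase PERK, at -0.25 ± 0.05, all called.

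By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 147 genes differed, 86 higher and 61 lower with Arg-TCA-4-1, 18 of them by at least 0.26 and 3 by at least 1. The adjusted p of edgeR's test was 1.89e-07 for EGR1, 2.27e-06 for FOSB, 4.89e-11 for DNAJB1 and 1.18e-22 for KCTD2. Cholesterol synthesis was higher, INSIG1 by 0.12 ± 0.03 (1 of 23, 2 adjusted over the list alone; camera adjusted p = 0.00111, and 0.0407 with an estimated correlation). The integrated stress response was lower, PPP1R15A at -0.19 ± 0.03 (1 of 28, 3 adjusted over the list alone; adjusted p = 0.00195, and 0.0407 with an estimated correlation).

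The other 7 lists past the threshold lost it with an estimated correlation. Ribosomal proteins were higher, RPL14 by 0.11 ± 0.02 and RPL22 by 0.10 ± 0.02 (7 of 74, 40 adjusted over the list alone; adjusted p = 5.32e-27, then adjusted p = 0.129), as were mitochondrial mRNAs with COX3 by 0.17 ± 0.03 and ATP8 by 0.15 ± 0.03 (4 of 13, 10 adjusted over the list alone; adjusted p = 1.69e-14, then adjusted p = 0.129). Hypoxia and glycolysis genes were lower, HK2 at -0.14 ± 0.03 and BNIP3 at -0.21 ± 0.05 (2 of 25, 8 adjusted over the list alone; adjusted p = 6.18e-07, then adjusted p = 0.349). The respiratory chain had 0 of 39 called and 2 adjusted over the list alone (adjusted p = 0.00111, then adjusted p = 0.346), with UQCRH at 0.08 ± 0.02 and COX4I1 at 0.07 ± 0.02. UQCRH was called with DESeq2 and without Arg-TCA-3-1 replicate 3, and COX4I1 in 2 of 8 other settings. Immediate early genes were higher with 4 of 18 (6 and 2 lower adjusted over the list alone; adjusted p = 0.00545, then adjusted p = 0.346), neuronal differentiation with TUBB3 by 0.21 ± 0.05 and NEFL by 0.09 ± 0.02 (2 of 19, 3 adjusted over the list alone; adjusted p = 0.0118, then adjusted p = 0.129), and p53 targets with SESN1 by 0.14 ± 0.03 (1 of 22, 6 adjusted over the list alone; adjusted p = 0.0175, then adjusted p = 0.393). The p53 list had an adjusted p of 0.147 without Arg-TCA-3-1 replicate 3, 0.228 without Arg-TCA-4-1 replicate 4 and 0.0569 without Arg-TCA-4-1 replicate 5.

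The other 20 lists did not pass (adjusted p from 0.0566 to 0.940). Of these, the proteasome list had an adjusted p of 0.0345 with the replicate number as a term and passed in 5 of 10 fits with a library left out, mesenchymal markers had an adjusted p of 0.0390 thinned to the smallest total and passed in 4 of 10, and 5 more lists passed in 1 to 3 of 10. TALDO1 was higher by 0.11 ± 0.02, SNHG8 stood at -0.24 ± 0.05 and GAS5 at -0.17 ± 0.04, all called. None of the genes named in advance was called, with CDKN1A at 0.11 ± 0.03 (adjusted p = 0.125), GRN at 0.01 ± 0.03, ASNS at -0.07 ± 0.02 and ETF1 at -0.02 ± 0.03. The count was 285 without Arg-TCA-4-1 replicate 1, 65 without Arg-TCA-4-1 replicate 5, 76 without Arg-TCA-3-1 replicate 2, 91 without Arg-TCA-3-1 replicate 4, 80 in a fit of only these 10 libraries, 250 with no count filter, 286 with DESeq2 and 288 with the replicate number as a term. Without single libraries some calls were lost, here with the range of the log2 fold change over the left-out libraries. GAS5 (-0.21 to -0.14) lost its call without Arg-TCA-3-1 replicate 4 or Arg-TCA-4-1 replicates 3 or 5, INSIG1 (0.10 to 0.14) without replicate 2 of either group, and RPL22 (0.08 to 0.11) without Arg-TCA-3-1 replicate 2 or Arg-TCA-4-1 replicate 5. HK2 (-0.17 to -0.13) lost it without Arg-TCA-3-1 replicates 1, 3 or 4 or Arg-TCA-4-1 replicates 2 or 5, and TUBB3 (0.19 to 0.24) without Arg-TCA-3-1 replicates 2 or 4 or Arg-TCA-4-1 replicates 2, 3 or 5. BNIP3 (-0.27 to -0.18) lost it without Arg-TCA-3-1 replicates 1, 3 or 4 or Arg-TCA-4-1 replicates 2, 3, 4 or 5, NEFL (0.08 to 0.11) without Arg-TCA-3-1 replicates 2, 4 or 5 or Arg-TCA-4-1 replicates 1, 2, 3 or 5, and SESN1 (0.12 to 0.16) without Arg-TCA-3-1 replicates 2, 3, 4 or 5 or Arg-TCA-4-1 replicates 2, 3, 4 or 5. INSIG1, RPL22, TUBB3, NEFL, SESN1 and BNIP3 also lost their call in a fit of only these 10 libraries, SESN1 and BNIP3 with libraries thinned to the smallest total, and BNIP3 with limma voom.

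The last question is whether transcripts that end in UGA, the codon both tRNAs read, changed together. The median log2 fold change of 5005 UGA genes minus that of 4968 UAA or UAG genes was 0.0025 for Arg-TCA-3-1, 0.00081 for Arg-TCA-4-1 and -0.00034 between the tRNAs. The camera test gave an adjusted p = 0.875 over the 3 comparisons for each, so no shift was detected. In a simulated data set for each comparison, with genes drawn independently of each other, a shift of 0.03 was detected. Correlation between genes and shifts as small as those measured were not simulated. By Fisher's exact test the share of UGA genes called did not differ from that of the other genes in any comparison and direction, the smallest p being 0.0640 for genes lower with Arg-TCA-4-1 (2.58% of UGA genes and 3.20% of the others).

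For the fixed lists that passed in none of the 3 comparisons with the preset correlation, called members are given in the order Arg-TCA-3-1 against empty vector, Arg-TCA-4-1 against empty vector and the tRNAs against each other, with the count adjusted over the list alone after each. Of all genes tested 3.56%, 4.22% and 0.954% were called. Of 19 genes of the unfolded protein response 3, 2 and 0 were called (3, 4 and 0), of 20 nonsense-mediated decay factors 2, 3 and 0 (4, 6 and 0) and of 34 transcripts sensitive to that decay 5, 5 and 3 (12, 10 and 7). Of 15 translation termination genes 0, 1 and 0 were called (0, 1 and 0), of 21 selenoproteins, whose UGA codon encodes selenocysteine, 3, 0 and 0 (5, 0 and 1), of 8 genes of the selenocysteine machinery 0, 1 and 0 (1, 2 and 0) and of 14 known stop codon readthrough genes 1, 0 and 0 (1, 1 and 0). None of 22 cytosolic aminoacyl-tRNA synthetases, 12 interferon and double-stranded RNA response genes, 8 epithelial and kidney line markers and 14 histones was called, also adjusted over the list alone. Of 28 proliferation genes 1, 1 and 0 were called (4, 1 and 0), of 25 autophagy and lysosome genes 2, 3 and 1 (8, 4 and 1) and of 12 frontotemporal dementia genes 0, 0 and 1 (5, 1 and 1). Of 13 adrenergic markers tested 1, 0 and 0 were called (1, 0 and 0) and of 22 mesenchymal markers 2, 2 and 0 (4, 3 and 6). The direction of the test, the median and the mean differed in sign for 8, 6 and 3 lists, none of them past the threshold.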

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

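The tests on KCTD2 and the count of adrenergic markers under 1 CPM were chosen only after the result was seen. Of 231 groups of 5 values examined, 18 held a library far from the others, where chance gives about 11.6. Arg-TCA-4-1 replicate 1 stood out in 4 of them, as did empty vector replicate 1. Arg-TCA-4-1 replicate 1 had 18985 genes with a count against 19249 to 19350 in its group, RARS1 at 133.96 CPM against 139.73 to 141.29, ETF1 at 224.74 against 241.72 to 244.76 and FSIP2 at 2.9022 against 2.0482 to 2.1683. Among empty vector libraries, replicate 4 was low for EGR1 (11.267 CPM) and SNORD139 (2.0636), replicate 5 was high for ZNF460 (9.1494) and LOC102724594 (29.425 against 0.58236 to 7.56), replicate 1 was high for HSPA5 (561.78), SNORA51 (1.5872), RPL23A (613.31) and UQCRH (256.8), and replicate 3 was high for STX1A (25.43). LOC102724594 was also high in Arg-TCA-4-1 replicate 4 (15.939 against 0.58377 to 0.8476), SNHG16 in Arg-TCA-4-1 replicate 2 (165.82) and NDUFB10 in Arg-TCA-4-1 replicate 5 (223.75). RPL22 was low in Arg-TCA-3-1 replicate 2 (371.99) and SESN1 high in Arg-TCA-3-1 replicate 1 (54.672).

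Other splits of the 10 libraries bear on each count. For Arg-TCA-3-1 against empty vector, 1 of 100 splits called as many genes as the real 549, and this was the real split. The highest other split called 3, so chance is argued against for that count. For Arg-TCA-4-1 against empty vector 2 of 100 did, the real 650 and a split with 679 that exchanged Arg-TCA-4-1 replicate 1 with empty vector replicate 2. Chance is argued against for that count too, but less clearly, as a split other than the real one called more genes. The count was 1291 without Arg-TCA-4-1 replicate 1 and 284 without Arg-TCA-4-1 replicate 5. For Arg-TCA-4-1 against Arg-TCA-3-1, 1 of 100 splits reached the real 147 and the highest other called 69, so chance is argued against there too. Chance cannot be excluded for the counts of gene lists: 23 of 100 splits gave 6 or more lists for Arg-TCA-3-1 against empty vector (highest other 10), 5 of 100 gave 10 or more for Arg-TCA-4-1 (highest other 11) and 15 of 100 gave 9 or more between the tRNAs (highest other 12). Splits that exchange 1 library per group keep most of the real grouping: of these 4 of 21, 3 of 17 and 8 of 21 gave as many lists, and of splits that exchange 2 per group 18 of 78, 1 of 82 and 6 of 78. Chance cannot be excluded for the stop codon shifts either, with 35, 79 and 91 of 100 splits as large as the real 0.0025, 0.00081 and 0.00034, and highest others of 0.00605, 0.0067 and 0.00636.

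Most fixed adrenergic markers lay near 0 in libraries labelled SH-SY5Y. Loss of counts around those genes in the authors' alignment or counting is argued against: of protein-coding genes within 250 kb of the 14 markers under 1 CPM, 62.3% stood at 1 CPM or more (exact 95% interval 49.8 to 73.7), against 66.1% of all protein-coding genes. The 13 of 25 markers under 1 CPM in every library raise doubt about the labelled line, but they are the pattern itself and no separate test of it. Cells of another line stay open, HEK293 among them, a human embryonic kidney line, named because IRS4 stood at 716.6 CPM with empty vector; this gene and line were chosen after the values were seen, 10 of 15 fixed epithelial and kidney line markers lay under 1 CPM in every library, and 14 of 27 fixed mesenchymal neuroblastoma markers had at least 10 CPM in every library. No reference profile of either line was used here, so no biological explanation was tested and the identity of the cells behind all values stays open.

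KCTD2 was higher with Arg-TCA-3-1 alone. A response to either plasmid is argued against by its log2 fold change of 0.031 with Arg-TCA-4-1, and a rise of the whole region by 11 tested neighbours within 150 kb, whose changes ran from -0.14 to 0.10. Plasmid sequence beside the tRNA gene could be counted as KCTD2, since 46 bases separate the tRNA gene from the next exon. Counts per gene do not show which exon was read, so this and a true rise of KCTD2 stay open.

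The fixed heat shock and immediate early lists were higher in both tRNA groups with the preset correlation, but with an estimated correlation the immediate early list with Arg-TCA-3-1 did not pass (adjusted p = 0.274). With the preset correlation a difference in depth is argued against, as all 4 tests held with every library thinned to the smallest total (highest adjusted p = 5.15e-05). GC content or length is argued against too, as all 4 held after a spline correction (highest adjusted p over these 4 tests = 9.25e-10). Chance values of the shared controls are argued against too, since both lists stayed higher in both comparisons in 20 of 20 assignments of split controls. An effect of the tRNAs stays open as a hypothesis, as do differences between plasmid preparations, which were not tested because each plasmid stands for a group.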

How the results depend on the processing

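Thinning to the smallest total, the stop codon fits with a library left out or with DESeq2 size factors, and the fit of Arg-TCA-3-1 without Arg-TCA-4-1 replicate 1 were chosen only after the result was seen. Of 78 called results under the rule for named genes, 60 kept their call in all fits that gave them an adjusted p. The other 18 lost it in at least 1, and none changed sign. HSPA6, CDHR4 and SNORD139 were among those with an adjusted p in 7 other settings, where EGR1 had 8. Of 37 uncalled results 8 were called in at least 1 other fit. Where no cause is named, the cause was not tested. Left-out libraries gave 333 to 900 called genes for Arg-TCA-3-1 against empty vector, 284 to 1291 for Arg-TCA-4-1 and 65 to 285 between the tRNAs, 2 to 7, 9 to 12 and 8 to 13 lists, and an r of 0.517 to 0.539 without an empty vector library, the tRNA libraries not being left out for r. Size thresholds of 1 and 0.26 left 20 and 95, 15 and 83, and 3 and 18 genes by construction. Fits of only the 10 libraries compared called 876 for Arg-TCA-3-1 and 80 between the tRNAs, where no count filter gave 250 and DESeq2 286. An estimated correlation left 1, 4 and 2 lists, and fry, which tests against no change, 3 between the tRNAs. Pearson's r fell to 0.470 with the CPM filter, where Spearman's rho rose to 0.566. With split controls r was 0.180 and rho 0.222.

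Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0497 to 0.0670 over 15 pairs, and 2 of 15 libraries correlated best with their own number. With the replicate block the counts were 743, 863 and 288.

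Left-out libraries moved the stop codon shift between 0.00088 and 0.0038, between -0.00054 and 0.0038, and between -0.0024 and 0.00069. In the same order it was 0.00079, -0.0024 and -0.0039 corrected for GC content and length, and 0.00595, -0.00035 and -0.0030 for UGA followed by C against other UGA genes (smallest adjusted p = 0.825). Uncalled genes near 0 changed sign. HSPA5 with Arg-TCA-3-1 was 0.0020 with no count filter, 0.00059 thinned and -0.012 to 0.0049 with a library left out; GADD45B with Arg-TCA-4-1 was 0.025 thinned and -0.038 to 0.016. With a library left out HSPA5 ran from -0.011 to 0.0045 with Arg-TCA-4-1 and from -0.0091 to 0.0081 between the tRNAs, where ATF4 ran from -0.0016 to 0.028, GRN from -0.0057 to 0.023 and ETF1 from -0.029 to 0.0044. At this depth and spread, with n = 5, 32% to 42% of simulated 1.1-fold changes were called; other depths were not simulated.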

Other observations

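All gene families in this part, the genes named from them and the values of chromosome 6 were chosen after the data were seen. Over 23 family definitions in 3 comparisons, 69 tests adjusted together, small nucleolar RNAs were higher with both tRNAs: 9 of 136 rose and 0 fell with Arg-TCA-3-1 (median log2 fold change 0.24; adjusted p = 0.00320 with an estimated correlation), and 10 rose and 1 fell with Arg-TCA-4-1 (0.19; adjusted p = 0.0198). SNORA66 rose by 1.18 ± 0.26 and 1.01 ± 0.27 and SNORD46 by 0.85 ± 0.18 and 0.73 ± 0.18. These RNAs are short, lie inside other genes and lack a poly-A tail, so their counts are uncertain in these libraries. Both comparisons use the same empty vector libraries, so the rises with both tRNAs are not independent. This family was not tested with split controls. Between the tRNAs 0 of its members rose and 0 fell.

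Zinc finger genes were lower with Arg-TCA-4-1, 32 of 478 falling and 2 rising under a narrow name pattern and 34 and 2 of 525 under a wider one (adjusted p = 0.0198 with an estimated correlation for both). Between the tRNAs 0 rose and 2 fell with Arg-TCA-4-1 under each pattern, with an adjusted p = 0.0948 for the narrow one and 0.0472 for the wider one. ZNF805 fell by 0.44 ± 0.05 and ZNF652 by 0.25 ± 0.04. Protein-coding genes under 5 kb were higher with Arg-TCA-4-1, 63 of 1233 rising and 7 falling (adjusted p = 0.0198), and higher than with Arg-TCA-3-1 too (26 and 2; adjusted p = 0.0472). GC content and transcript length together accounted for 0.108 of the variance of t over genes with Arg-TCA-4-1 and 0.0415 with Arg-TCA-3-1. No gene family was corrected for them, the zinc finger genes and the genes under 5 kb included. Of the fixed lists, only the heat shock and immediate early lists were corrected. Of 1153 genes over 200 kb 1 rose and 25 fell with Arg-TCA-4-1 (camera adjusted p = 0.689 with an estimated correlation).

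Between 29 and 33 Mb of chromosome 6, 63 of 139 protein-coding genes had no count in any library and the median total was 1, against 48 of 855 and a median of 4378 on the rest of the chromosome. HSPA1A, HSPA1B, RPS18 and TUBB held 75, 90, 8 and 2 counts over 15 libraries, too few for a test. Of 75 cytosolic ribosomal protein genes 72 stood at 10 CPM or more in every library, so totals such as that of RPS18 are not taken as levels of expression, and why they are low was not tested.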
